A study of Mus musculus with 3 samples.

How the data were processed

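The deposited matrices held 1 count of unique molecular identifiers (UMIs) per gene and cell barcode, stated as count output of Cell Ranger 4.0.0 per the file headers. Reads were aligned to mm10 according to the submitters' processing notes. The annotation release and the way cell barcodes were chosen were not given in the sources used here. Libraries were 10x Genomics 3' libraries, 1 per FGF4 dose. Cells were detached with trypsin or Accutase, and which was used for each library was not given in the sources used here. Coordinates came from GENCODE M21 (GRCm38, the same assembly as mm10), in which 32235 gene identifiers matched, 31502 of them with the same symbol.

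UMIs were summed over all cells of a library and scaled to the library total as CPM. Ratios between libraries carried 95% conditional binomial intervals, levels carried exact Poisson intervals and shares carried exact binomial intervals, all for counting error only. Where 0 cells had a UMI, the limit given was the share that 3 cells would make up. Genes with at least 20 CPM in the higher library of a comparison were considered, and differences of at least 2-fold were counted. No test between doses was made, because each dose was 1 library. A sum of 0 UMIs was set to 3 UMIs when log2 ratios were formed, equal to 0.0702, 0.0399 and 0.0369 CPM at 0, 5 and 50 ng/ml.

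Named genes were the 12 with the largest ratio in each direction among those with at least a 2-fold ratio and a counting interval that excluded 1, with members of the gene lists added. Symbols of predicted genes (Gm or AC plus digits, or ending in Rik) and ribosomal protein genes were left out. The 10 genes with the largest gain and the 10 with the largest loss of Fano factor from 0 to 50 ng/ml were named without that exclusion. Results for some genes that met these rules are not reported here. In all, 29 gene lists were fixed beforehand, covering FGF and ERK, immediate early, naive, general and formative pluripotency, primitive endoderm, primitive streak, neuroectoderm, trophectoderm, 2-cell-like, germline, Wnt, Nodal, BMP, FGF ligand and receptor, LIF, S phase, G2/M, p53, glycolysis, cholesterol, ATF4, heat shock, mitochondrially encoded, epithelial and mesenchymal, imprinted, DNA methylation, retinoid and fibroblast genes. A member was measured if it reached 5 CPM in at least 1 of the 3 libraries. List medians were placed among 10000 random lists of the same size matched on mean level in 20 bins.

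Variation among cells was read after thinning each cell to 7000 UMIs, with 369, 794 and 896 cells kept and the shallower cells left out. Distance was the mean of 1 minus the Pearson correlation of log2 UMIs with a pseudocount of 1, over genes with at least 0.2 UMI per cell. Fano factors were compared for genes with at least 0.5 UMI per cell whose means in both libraries were within 1.25-fold. The cell filter left out cells with more than 10% mitochondrial UMIs, or with UMIs more than 3-fold below or above the library median, which kept 359, 706 and 798 cells. The depth of the libraries was 42726514, 75184072 and 81409975 UMIs in all, so the floor of 3 UMIs lay far below the 20 CPM limit. Summed counts of a gene list across cells were read as Fano factors and coefficients of variation.

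Doublets were called per library with Scrublet as in scanpy. It called 12, 7 and 26 cells, the main results keep all cells, and an alternative leaves called doublets out. Clusters were found per library with Leiden at resolution 0.5 on 20 principal components of 2000 variable genes and 15 neighbours, after scaling to 10000 UMIs per cell, and were compared with 8 marker lists.

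The unit, comparisons, thresholds, gene lists, thinning to 7000 UMIs, the cell filter and 1 set of alternatives were fixed before the data were examined. Those alternatives were other scalings (TMM, median of ratios, mean share per cell, totals without mitochondrial and ribosomal genes), other levels and fold limits, a second seed, a depth of 3500 UMIs, equal numbers of cells, Spearman correlation, square-root values, a higher minimum level for variation, excess variation in place of Fano factors, no matching of means, cells at full depth, removal of cell-cycle genes, removal of doublets and another cluster resolution. Thinning filtered cells to 63000 UMIs, its sub-settings and the naive-list variation alternatives were chosen after seeing the data. That deeper setting kept 342, 659 and 719 cells.

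A self-test on artificial libraries with known differences covered the true ratio in 95.0% of intervals over 5396 genes. It placed 100% of genes set 4-fold or 2.5-fold higher and 0% of genes set 1.5-fold higher beyond 2-fold, and 0 of 5196 unaltered genes. With equal noise the distance difference was -0.00166, and with squared variation of 0.4 against 0.2 it was 0.0487. The median log2 Fano ratio was 0.00286 for equal noise and 0.269 for unequal noise. The raised gene list stood at percentile 100, and 0 of 40 random lists fell outside the middle 95%.

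Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors, which were 1.01, 1.01 and 0.984.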

Results

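Fgf4 itself was read first, because all 3 libraries came from Fgf4-deficient mouse embryonic stem cells. Transcripts assigned to Fgf4 (ENSMUSG00000050917, mm10 7:144847367-144865243, plus strand) were present at every dose, with 2208 UMIs without FGF4, 1874 at 5 ng/ml and 1664 at 50 ng/ml. These corresponded to 51.7 CPM (UMIs scaled to library totals, 95% interval 49.5 to 53.9), 24.9 CPM (23.8 to 26.1) and 20.4 CPM (19.5 to 21.4). Fgf4 transcript was thus 2.07-fold lower (1.95 to 2.21) at 5 ng/ml and 2.53-fold lower (2.37 to 2.70) at 50 ng/ml than without ligand. A 3' tag outside the deleted part of the gene would still be counted, so these values check nothing about the loss of FGF4 protein.

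The 3 libraries held 2222 cells, with 373 cells at 0 ng/ml, 874 at 5 ng/ml and 975 at 50 ng/ml FGF4. All cells had spent 24 h in N2B27 with the GSK3 inhibitor Chiron and heparin, so only the FGF4 dose was meant to differ. Median UMIs per cell were 107873, 91764 and 87334, and median detected genes were 8410, 7970 and 7737. Each dose was 1 library, there were no replicates, and cells are not replicates of a dose. Every interval below therefore covers counting error only, and "higher" and "lower" describe these libraries.

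Rankings of genes cover those with at least 20 CPM in the higher library, with predicted and ribosomal protein genes left out. At 50 ng/ml the 2 such genes furthest above their level without FGF4 were Spry4 and Etv4, both known targets of ERK signalling. Spry4, a Sprouty inhibitor of receptor tyrosine kinase signalling (ENSMUSG00000024427, 18:38586247-38601415, minus strand), was 31.1 CPM (29.9 to 32.3) against 0.0702 CPM (0.0145 to 0.205). Its ratio of 442 rested on 3 UMIs in the library without ligand, and its interval ran from 151 to 2147. Etv4, an ETS-family transcription factor (ENSMUSG00000017724, 11:101769742-101785371, minus strand), was 88.9 CPM (86.9 to 91.0) against 1.17 CPM (0.869 to 1.54). That made Etv4 76.0-fold higher (57.6 to 102). Dnmt3l, the catalytically inactive partner of the de novo DNA methyltransferases (ENSMUSG00000000730, 10:78041947-78063622, plus strand), was 12.5-fold higher (11.5 to 13.6), at 170 CPM (168 to 173) against 13.6 CPM (12.6 to 14.8).

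The other leading genes at 50 ng/ml had varied known functions. Gja1, which encodes the gap-junction protein connexin 43, was 11.6-fold higher (10.3 to 13.1), and the paternally expressed retrotransposon-derived gene Peg10 was 11.4-fold higher (9.60 to 13.7). The nucleotide-hydrolysing ectoenzyme gene Enpp3 was 10.97-fold higher (8.90 to 13.7), the tetherin gene Bst2 was 10.4-fold higher (8.92 to 12.2) and the focal-adhesion gene Zyx was 10.1-fold higher (8.32 to 12.4). Lef1, a nuclear partner of beta-catenin, was 10.0-fold higher (9.05 to 11.2). The amino-acid transporter Slc7a7 was 9.96-fold higher (8.97 to 11.1), the zinc transporter Slc39a14 was 7.91-fold higher (6.63 to 9.52), and the pluripotency-associated chromatin gene Utf1 was 7.79-fold higher (7.44 to 8.16).

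Among genes with at least 20 CPM in the higher library, those furthest below the level without ligand were led by Calcoco2. This gene encodes an autophagy receptor (ENSMUSG00000006056, 11:96099326-96111964, minus strand). It was 15.7 CPM (14.9 to 16.6) at 50 ng/ml against 185 CPM (181 to 189), or 11.8-fold lower (11.1 to 12.5). The cation channel Trpm1 was 9.82-fold lower (8.47 to 11.4), the myelin-associated gene Mobp was 9.23-fold lower (8.42 to 10.1) and the ubiquitin ligase Rnf213 was 9.0-fold lower (8.0 to 10.1). The transcriptional repressor Hes1 was 6.72-fold lower (6.27 to 7.22) and the Wnt-binding protein gene Sfrp1 was 5.78-fold lower (5.30 to 6.32). The respiratory-chain subunit Cox7a1 was 5.30-fold lower (4.94 to 5.69), the water channel Aqp3 4.68-fold lower (4.18 to 5.24) and the basement-membrane gene Nid1 4.31-fold lower (3.94 to 4.72). Egr1, an immediate early gene, was 4.26-fold lower (3.91 to 4.64), the inositol kinase Itpka 4.21-fold lower (3.85 to 4.60) and the receptor tyrosine kinase Kit 4.15-fold lower (3.92 to 4.39).

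Among 5709 genes with at least 20 CPM in either library, 113 were at least 2-fold higher and 116 at least 2-fold lower at 50 ng/ml than without FGF4. The middle 95% of log2 ratios ran from -0.90 to 0.87, so most transcripts lay within 2-fold of their level without ligand.

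The FGF and ERK response list had the largest median of the signalling lists. Of its 15 measured members, 11 were at least 2-fold higher at 50 ng/ml and 1, Egr1, was at least 2-fold lower, and the list median log2 ratio was 1.62. The ERK phosphatase genes Dusp6 and Dusp4 were 11-fold (8.70 to 14.2) and 11.3-fold (8.41 to 15.6) higher, Myc was 11.6-fold higher (9.14 to 14.9) and Spry2 was 7.38-fold higher. Etv5 differed from its relative Etv4, at 188 CPM against 186 CPM, a ratio of 1.01 (0.985 to 1.04). Among 10000 random lists matched for level, the median of this list stood at percentile 100. That placement, like every percentile given, describes these libraries.

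Naive pluripotency genes were lower at 50 ng/ml and formative genes were higher. Nanog, a core naive factor (ENSMUSG00000012396, 6:122707489-122714633, plus strand), was 103 CPM (101 to 105) against 280.5 CPM (275 to 286), or 2.72-fold lower (2.64 to 2.80). Tfcp2l1 was 2.97-fold lower (2.87 to 3.08), Tbx3 2.47-fold lower (2.37 to 2.58), Prdm14 5.54-fold lower (4.67 to 6.59) and Spic, at 0.381 CPM against 10.4 CPM, 27.4-fold lower (19 to 40.7). Of 21 measured naive genes, 7 were at least 2-fold lower and 1, Gbx2, was at least 2-fold higher, at 2.88-fold (2.65 to 3.13). Zfp42 was 484 CPM against 454 CPM. The naive median log2 ratio was -0.87, at percentile 0 of the matched lists, and was -0.38 over members with at least 20 CPM.

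Formative genes, which mark the exit from the naive state, had a median log2 ratio of 0.96, and 5 of 11 were at least 2-fold higher at 50 ng/ml. Otx2 was 7.46-fold higher (5.94 to 9.48), the methyltransferase Dnmt3b 3.27-fold higher (3.14 to 3.42), the transcription factor Tcf15 5.26-fold higher (4.88 to 5.67) and Pou3f1 3.47-fold higher (2.88 to 4.20). General pluripotency genes also lay above their level without ligand, with a median log2 ratio of 0.80. Pou5f1 was 379 CPM against 203 CPM, or 1.86-fold higher (1.82 to 1.91), and Lin28a was 2.38-fold higher (2.29 to 2.47), whereas Sox2 was 1.26-fold lower.

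Lists for later lineages were mixed at 50 ng/ml. Of the 15 primitive-streak genes 6 were measured, and 5 of these were at least 2-fold higher. Among them were T at 4.33-fold (3.58 to 5.28), Eomes at 4.01-fold and Fst at 7.17-fold (5.66 to 9.21), and the median log2 ratio was 1.95. These began from low levels, and T was 12.2 CPM against 2.81 CPM. The primitive-endoderm list lay below its level without ligand, with a median log2 ratio of -0.75 over the 8 measured of its 21 genes. Its basement-membrane members led, with Lama1 7.08-fold lower (5.82 to 8.66) and Fn1 1.76-fold lower, while the endocytic receptor Lrp2 was 2.03-fold higher. The lineage regulators Gata6, Gata4 and Sox17 did not reach the level needed to be measured, so this median does not speak for them. The neuroectoderm median log2 ratio was -0.87 over 4 genes, with Tubb3 27.6 CPM against 107 CPM and Nes 3.65-fold lower, although Sox3 was 1.59-fold higher. The trophectoderm median log2 ratio was 0.53 over 4 genes, and was -0.82 when only members with at least 20 CPM were read. Its 2 higher members, Cdx2 at 3.71-fold and Eomes, also belong to the primitive-streak list, whereas Tfap2c and Tead4 were 1.77-fold and 1.82-fold lower.

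Imprinted genes also lay above their level without ligand at 50 ng/ml, with 6 of 11 at least 2-fold higher and a median log2 ratio of 1.40. The maternally expressed noncoding RNAs of the Dlk1-Dio3 domain were all higher. Meg3 (ENSMUSG00000021268, 12:109541001-109571726, plus strand) was 220.0 CPM (217 to 223) against 46.8 CPM (44.7 to 48.9), or 4.70-fold higher (4.49 to 4.93). Rian (ENSMUSG00000097451, 12:109603940-109661716, plus strand) was 4.47-fold higher (4.13 to 4.85) and Mirg 4.39-fold higher (3.69 to 5.26). Of the paternally expressed members, Snrpn was 2.63-fold higher (2.56 to 2.71) and Mest 2.97-fold higher (2.74 to 3.22), whereas Peg3 was 1.13-fold higher and Impact 1.02-fold lower. The maternally expressed Igf2r was 1.11-fold lower. Dnmt1, the maintenance methyltransferase, was 151 CPM against 148 CPM. The 7-gene DNA methylation list had a median log2 ratio of 0.16, with 5 members higher and 2 lower. Of these, 2 were at least 2-fold higher, Dnmt3l and Dnmt3b.

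Signalling lists other than FGF and ERK had members on both sides at 50 ng/ml. The Nodal list had a median log2 ratio of -0.44, with Lefty1 3.25-fold lower (3.09 to 3.41) and Lefty2 3.49-fold lower (3.21 to 3.80) but the co-receptor gene Tdgf1 2.65-fold higher. BMP targets had a median log2 ratio of 0.18, where Id1 and Id3 were 4.94-fold (4.00 to 6.18) and 4.69-fold (4.32 to 5.09) higher and Id4 6.62-fold lower (5.50 to 8.0). The FGF ligand and receptor list stood at -0.96 over 4 of its 9 genes, including Fgf4 itself. Fgfr2 was 3.99-fold lower (3.41 to 4.67) and Fgfr1 1.51-fold lower, whereas Fgf17 was higher, at a log2 ratio of 0.86. The LIF list stood at -0.57, with Il6st 1.72-fold lower and Stat3 1.49-fold lower. The immediate early list stood at -0.60 over 5 of its 12 genes, with Klf6 1.52-fold lower and Ier2 1.37-fold higher. Wnt targets were near even at -0.04, a sign that was opposite under some alternative scalings. Axin2 was 39.2 CPM against 38.2 CPM, Cdx1 2.56-fold higher (2.41 to 2.71) and Notum 1.67-fold lower.

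Glycolysis genes had a median log2 ratio of 0.27 at 50 ng/ml, with the pyruvate dehydrogenase kinase Pdk1 7.17-fold higher (6.61 to 7.78) and Ldha 1.80-fold higher but the glucose transporter Slc2a3 1.43-fold lower. The retinoid list had a median of 0.64, with Rarg 1.56-fold higher. S-phase genes stood at 0.11, with Ccne1 1.74-fold higher, and G2/M genes at -0.17. The p53 list stood at -0.29, with Cdkn1a 1.56-fold lower and Mdm2 1.41-fold lower. Medians of 0.02 for cholesterol synthesis, 0.15 for ATF4 targets, 0.11 for germline genes, 0.08 for mitochondrially encoded genes, -0.01 for heat shock and -0.04 for epithelial and mesenchymal genes all took the opposite sign under at least 1 alternative scaling or cell choice. Within the last list Epcam was 2.64-fold higher (2.51 to 2.78), Cdh1 1.45-fold lower and Vim 180.2 CPM against 189 CPM. None of the 12 fibroblast genes, listed in case feeder cells were present, reached the level needed to be measured.

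**Figure D1:**
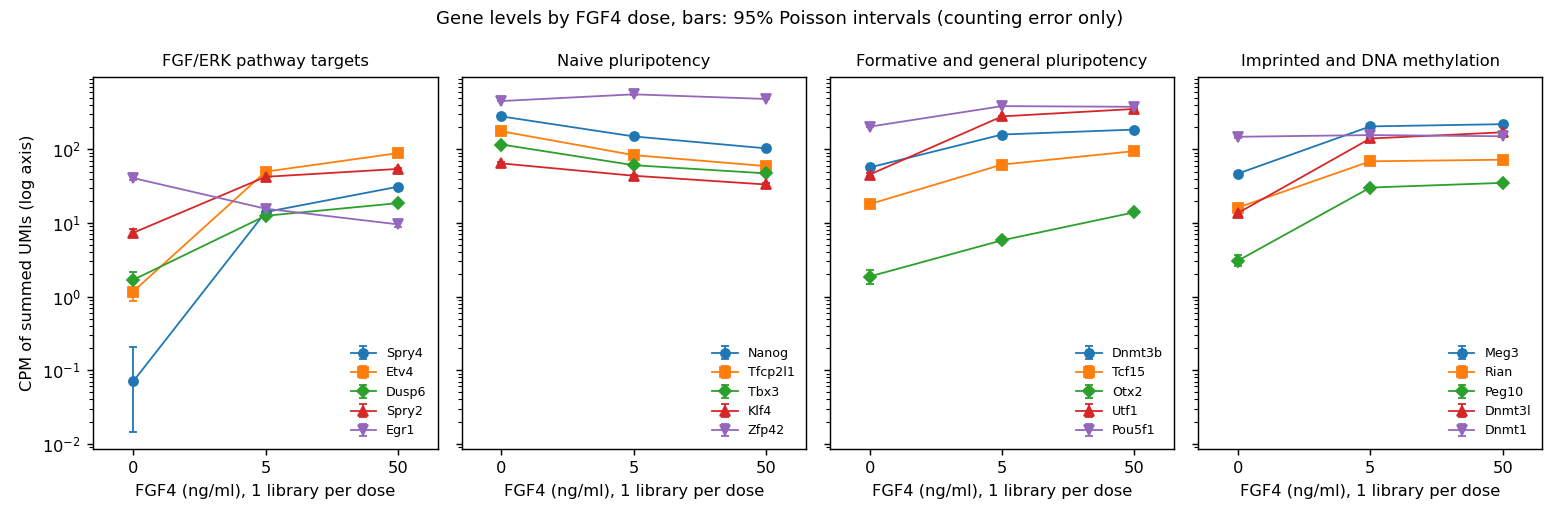
Transcript level in CPM (log axis) against FGF4 dose (0, 5 and 50 ng/ml) for FGF and ERK response, naive, formative and general pluripotency, and imprinted or DNA methylation genes, where points are library totals, bars are 95% Poisson intervals and lines join the doses of a gene. Etv4 stood at 1.17, 49.8 and 88.9 CPM and Nanog at 280.5, 149.9 and 103 CPM.

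At 5 ng/ml most of the same genes already lay far from their level without FGF4. Etv4 was 42.5-fold higher (32.2 to 57.4), at 49.8 CPM (48.2 to 51.4), and Spry4 was 14.1 CPM (13.2 to 14.9), a ratio of 200.4 (68.4 to 973) against the same 3 UMIs. The gap-junction gene Gja1 was 10.5-fold higher (9.31 to 11.9), Dnmt3l 10.3-fold higher (9.47 to 11.2), Peg10 9.87-fold higher (8.28 to 11.9) and Lef1 8.30-fold higher (7.48 to 9.24). Bst2 was 7.73-fold higher (6.62 to 9.06), Slc7a7 7.44-fold higher (6.69 to 8.28), Pdk1 6.25-fold higher (5.76 to 6.79) and Utf1 6.18-fold higher (5.90 to 6.48). The transcription factor Sox11 was 6.02-fold higher (5.29 to 6.87), the feedback inhibitor Spry2 5.76-fold higher (5.13 to 6.49) and the G1 cyclin Ccnd2 5.55-fold higher (4.96 to 6.23).

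On the lower side at 5 ng/ml, Calcoco2 again led among genes with at least 20 CPM in the higher library, at 7.64-fold lower (7.26 to 8.04). Rnf213 was 5.62-fold lower (5.08 to 6.23), Mobp 5.62-fold lower (5.2 to 6.08), Trpm1 5.50-fold lower (4.88 to 6.23) and Hes1 4.35-fold lower (4.09 to 4.62). The channel gene Aqp3 was 3.92-fold lower (3.52 to 4.37), Cox7a1 3.64-fold lower (3.42 to 3.88), Sfrp1 3.61-fold lower (3.35 to 3.90) and Itpka 3.60-fold lower (3.30 to 3.92). The basement-membrane gene Nid1 was 3.42-fold lower (3.14 to 3.72) and the neuronal tubulin gene Tubb3 3.41-fold lower (3.25 to 3.59). Among 5691 genes considered, 80 were at least 2-fold higher and 75 at least 2-fold lower at 5 ng/ml.

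The gene lists at 5 ng/ml were placed on the same sides as at 50 ng/ml for the main groups. The FGF and ERK list had a median log2 ratio of 1.48, with Dusp6 7.43-fold higher (5.84 to 9.58), Myc 7.93-fold higher (6.23 to 10.2) and Egr1 2.61-fold lower (2.42 to 2.81). Naive genes stood at -0.54, with Nanog 1.87-fold lower (1.82 to 1.92), Tfcp2l1 2.11-fold lower, Tbx3 1.91-fold lower and Dppa3 2.32-fold lower. Formative genes stood at 0.85, with Dnmt3b 2.80-fold higher (2.68 to 2.93), Tcf15 3.45-fold higher (3.19 to 3.73) and Otx2 3.1-fold higher (2.44 to 3.99). General pluripotency genes stood at 0.68, with Pou5f1 1.90-fold higher (1.86 to 1.95), and imprinted genes at 1.21, with Meg3 4.39-fold (4.19 to 4.60) and Rian 4.26-fold (3.93 to 4.61) higher. Primitive-streak genes stood at 1.52, with T 3.39-fold higher (2.79 to 4.15).

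The other lists at 5 ng/ml lay on both sides of their level without ligand. Medians were -0.58 for primitive endoderm, -0.82 for neuroectoderm, -0.73 for FGF ligands and receptors, -0.43 for the LIF list, -0.30 for Nodal and -0.34 for immediate early genes, including Lama1 4.80-fold lower and Fgfr2 2.96-fold lower. Glycolysis stood at 0.19, retinoid genes at 0.49, DNA methylation at 0.21, BMP targets at 0.19, S phase at 0.15, G2/M at -0.14 and p53 targets at -0.17. The trophectoderm median of 0.47 was -0.56 when only members with at least 20 CPM were read. The cholesterol synthesis median was 0.05 and the heat shock median -0.05. Medians of 0.01 for Wnt targets, 0.06 for ATF4 targets, 0.15 for germline genes, 0.12 for mitochondrially encoded genes and -0.01 for epithelial and mesenchymal genes took the opposite sign under at least 1 alternative.

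**Figure D2:**
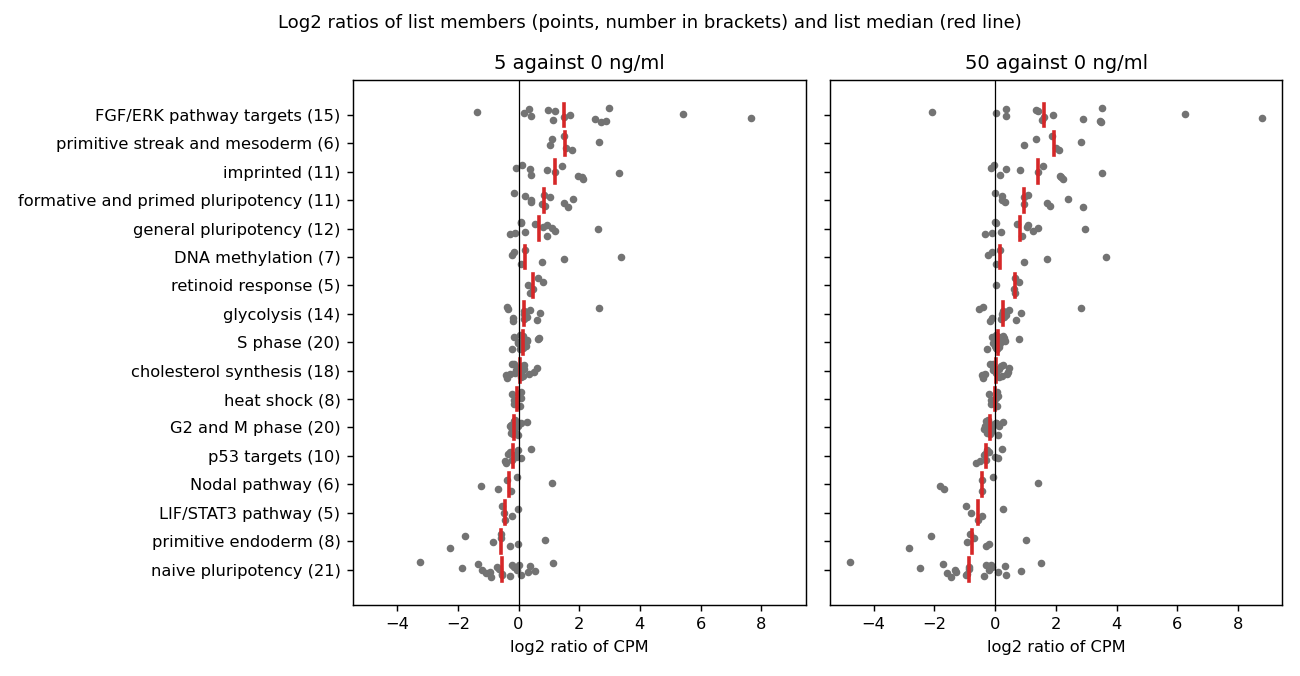
Log2 ratio of CPM for members of 17 gene lists at 5 and at 50 ng/ml FGF4 relative to 0 ng/ml, where each point is a gene and each red line is the list median. The FGF and ERK medians were 1.48 and 1.62 and the naive medians were -0.54 and -0.87, and both kept their sign under every alternative scaling.

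Between 5 and 50 ng/ml few transcripts were 2-fold apart. Of 5501 genes, 4 were at least 2-fold higher and 3 at least 2-fold lower at 50 ng/ml. Spry4 was 2.21-fold higher (2.05 to 2.37), and Zscan4d, a gene of the 2-cell-like programme, was 7.99-fold higher (6.89 to 9.31), at 20.9 CPM against 2.62 CPM. The 1% of cells with most 2-cell-like UMIs held at least 95.4% of them in every library, so this ratio rests on a handful of cells and carries no dose order. The other 2 higher genes were the predicted genes Gm5662 and Gm21761, named after the values were seen. Both stood with Zscan4c and Zscan4d among the leading genes of the same cell cluster at 50 ng/ml. Whether they rest on the same few cells was not tested. The Nodal inhibitor Lefty1 was 2.02-fold lower (1.93 to 2.12) and the small noncoding RNA gene Bc1 2.68-fold lower (2.54 to 2.84). Bc1 stood at 17.1, 57.1 and 21.3 CPM across the doses, so its levels did not follow dose order.

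Members of the same groups also differed between the doses. Etv4 was 1.79-fold higher (1.72 to 1.86), Tcf15 1.53-fold higher (1.47 to 1.58), Dusp6 1.48-fold higher (1.37 to 1.61) and Otx2 2.40-fold higher (2.15 to 2.69) at 50 than at 5 ng/ml. Nanog was 1.45-fold lower (1.41 to 1.49) and Egr1 1.63-fold lower (1.49 to 1.79). The median log2 ratio between 50 and 5 ng/ml was 0.36 for the FGF and ERK list, 0.19 for formative genes, 0.29 for primitive-streak genes, -0.16 for naive genes and 0.07 for imprinted genes. General pluripotency genes stood at 0.03. The middle 95% of all genes ran from -0.28 to 0.20.

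The genes placed at least 2-fold from the level without ligand were largely shared by the doses. Of 5655 genes considered in both comparisons, 94 were higher at 50 ng/ml and 80 at 5 ng/ml, and 72 were higher in both, where 1.33 would fall together if independent. On the lower side 116 and 75 genes gave 68 in common, where 1.54 would fall together if independent. Both comparisons shared the same library without ligand, and 100 simulations with counting noise alone gave an overlap of 0. That value is no measure of what the shared library adds, because counting noise at these levels gives no 2-fold difference. Log2 ratios correlated at 0.921 between the comparisons, where the simulated value was 0.654, and their covariance was 0.165, where the simulated value was 0.00104. The control could not be split into separate libraries, so part of the excess may come from anything particular to that 1 library.

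The genes at least 2-fold apart at 50 ng/ml were often intermediate at 5 ng/ml, which choosing them at 50 ng/ml favours. Of the 113 higher genes, 103 lay between their levels at 0 and 50 ng/ml, and of the 116 lower genes 114 did. The median log2 ratio of the 113 genes was 1.26 at 5 and 1.47 at 50 ng/ml, and that of the 116 genes was -1.05 and -1.32. Tcf15, at 18.0, 62.1 and 94.8 CPM, and Otx2, at 1.87, 5.81 and 14.0 CPM, were graded examples, whereas Meg3, at 46.8, 205 and 220.0 CPM, lay close to its upper level by 5 ng/ml.

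The share of cells with a UMI of the main markers also differed between doses. Cells were thinned to 7000 UMIs each, which left out 4, 80 and 79 cells at 0, 5 and 50 ng/ml. A Nanog UMI was then present in 80.8% (76.4 to 84.7), 57.1% (53.5 to 60.5) and 44.3% (41.0 to 47.6) of cells, against 98.1%, 86.6% and 83.5% without thinning. Both settings keep the mitochondria-rich cells, which were more frequent with FGF4, and in filtered cells at 63000 UMIs the Nanog shares were 99.7%, 97.7% and 95.8%. Unthinned shares were lower with FGF4 even for Zfp42, at 97.9%, 92.3% and 91.4%, whose CPM was not, so part of the unthinned Nanog difference may go with cell quality. An Etv4 UMI was present in 0.542%, 27.5% (24.4 to 30.7) and 43.9% (40.6 to 47.2) of thinned cells, and in 7.77%, 77.1% and 86.6% of cells without thinning. Spry4 was seen in 0 of 369 cells (up to 0.813%), 8.19% and 18.6%, against 0.804%, 44.7% and 64.9% without thinning. Hba-a1 and Alb, which these cells do not make, were absent from all thinned cells (up to 0.813%, 0.378% and 0.335%), and Hba-a1 was present in 1.07%, 0.458% and 0.205% of cells without thinning. These genes do not measure free RNA of expressed genes in the droplets, so the shares are of cells with a UMI and not of cells expressing a gene.

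Tfcp2l1 followed Nanog, with thinned shares of 68.3%, 39.8% and 31.3% (97.9%, 83.1% and 81.5% without thinning). Egr1 was seen in 18.4%, 7.93% and 6.58% of thinned cells and 59.5%, 34.7% and 26.3% without thinning. Otx2 was seen in 1.63%, 3.78% and 7.59% of thinned cells and in 14.7%, 21.9% and 33.9% without thinning, and Dnmt3b in 26.8%, 61.0% and 69.1% of thinned cells. The unthinned Dnmt3b shares of 93.8%, 87.9% and 89.1% ran against its CPM and carry no order. The lineage markers Gata6, Gata4, Sox17, Pdgfra and Sox1 were each seen in less than 1% of thinned cells at every dose, so no order was read from them.

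Over all cells, cell-to-cell distance was greater with FGF4, but cell quality accounted for most of the difference. The mean of 1 minus the Pearson correlation between thinned cells, over 4370 genes, was 0.354 without FGF4, 0.381 at 5 ng/ml and 0.372 at 50 ng/ml. Cells with more than 10% mitochondrial UMIs made up 3.22% (1.67 to 5.55), 15.2% (12.9 to 17.8) and 15.7% (13.5 to 18.1) of the libraries. With these and cells of extreme depth left out, a filter fixed before the data were examined, the distances were 0.346, 0.351 and 0.348. The differences from the library without ligand were then 0.00506 and 0.00209, instead of 0.0267 and 0.0174. Thinning filtered cells to 63000 UMIs, a depth chosen after these results were seen, gave 0.204, 0.201 and 0.196 over 10053 genes, a lower distance with FGF4. The all-gene distance thus gave no direction that held in every setting.

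Variance relative to the mean of single genes had the same dependence on cell quality. The median log2 ratio of Fano factors relative to 0 ng/ml, among genes of matched level, was 0.07 at 5 and 0.07 at 50 ng/ml over all cells. Among filtered cells it was 0.00106 and 0.00252, with 50.6% and 50.7% of genes higher, and between 50 and 5 ng/ml it was 0.00392. Single genes still differed, as the adenine nucleotide carrier Slc25a4 had a Fano factor of 1.66 without FGF4 and 3.62 at 50 ng/ml over all cells, and of 1.64 and 3.59 in filtered cells. At 63000 UMIs the Slc25a4 ratio was 4.08, and 3.95 without the cell richest in it in each library. The small nucleolar host gene Snhg1 stood at 6.10 and 1.32 over all cells, but there 1 cell carried the difference, because at 63000 UMIs its 6.14-fold lower Fano factor was 1.09-fold lower without the richest cell in each library. Over all cells mt-Nd3 stood at 17.4 and 33.4, but in filtered cells at 63000 UMIs it stood at 6.88 and 5.05, a setting that differs in both cells and depth.

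Relative to its mean, the summed level of naive genes varied more between cells with FGF4 in every setting tried. This pattern was picked out after the values of 29 lists were seen. The coefficient of variation of the summed naive list was 28.8%, 37.0% and 35.3% over all cells and 27%, 31.8% and 30.3% among filtered cells. In cells thinned to 63000 UMIs it was 21.4%, 26.6% and 25.1%, at mean sums of 360, 303 and 281 UMIs. At an equal Fano factor this coefficient is greater where the mean is lower, so it does not separate variation from level. Dppa5a made up much of the sum, at means of 209, 180 and 170 UMIs. Counting noise was then removed gene by gene, and 15 of 19 naive members had a greater excess variation at 50 ng/ml than without ligand. Among 4974 genes of matched level with excess variation in both libraries, 45.1% did. The naive members were not matched on level. At an equal Fano factor above 1 this measure is greater where the mean is lower, so the count does not separate variation from level. Nanog had a squared coefficient of variation beyond counting noise of 0.167, 0.338 and 0.454, and Tfcp2l1 of 0.136, 0.288 and 0.466, while the Fano factor of Nanog stayed at 3.97, 4.20 and 4.07. Lower mean levels of both genes were therefore tied to greater relative variation.

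Several other lists had a lower coefficient of variation of their summed level with FGF4 at this depth, a measure that here too was not matched on level. The coefficient of variation of the summed FGF and ERK list was 33.7%, 25.4% and 25.9%, that of Nodal genes 65.5%, 46.2% and 39.2%, and that of imprinted genes 41.2%, 35.0% and 33.7%. Single members of the Nodal list went the other way, as 5 of 6, Lefty1 and Nodal among them, had a greater excess variation at 50 ng/ml. Excess variation at 50 ng/ml was greater in 3 of 8 FGF and ERK members, 2 of 9 imprinted members and 3 of 14 glycolysis members. The median log2 ratios of these lists were above 0, and their members were not matched on level either. The coefficient of variation of the summed glycolysis list was 17.9%, 15% and 14.6%. The neuroectoderm list, at 56.2%, 77.9% and 103%, and the primitive-endoderm list, at 28.6%, 34.5% and 36.7%, had more variation of their summed level, with counting noise included. Without counting noise, 3 of 5 primitive-endoderm members had a greater excess variation at 50 ng/ml, and their median excess was 0.292 without FGF4 and 0.274 at 50 ng/ml. In the formative list 2 of 7 members had a greater excess variation at 50 ng/ml. In the p53 list 7 of 10 did, and their median excess was 0.272 without FGF4 and 0.353 at 50 ng/ml.

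**Figure D3:**
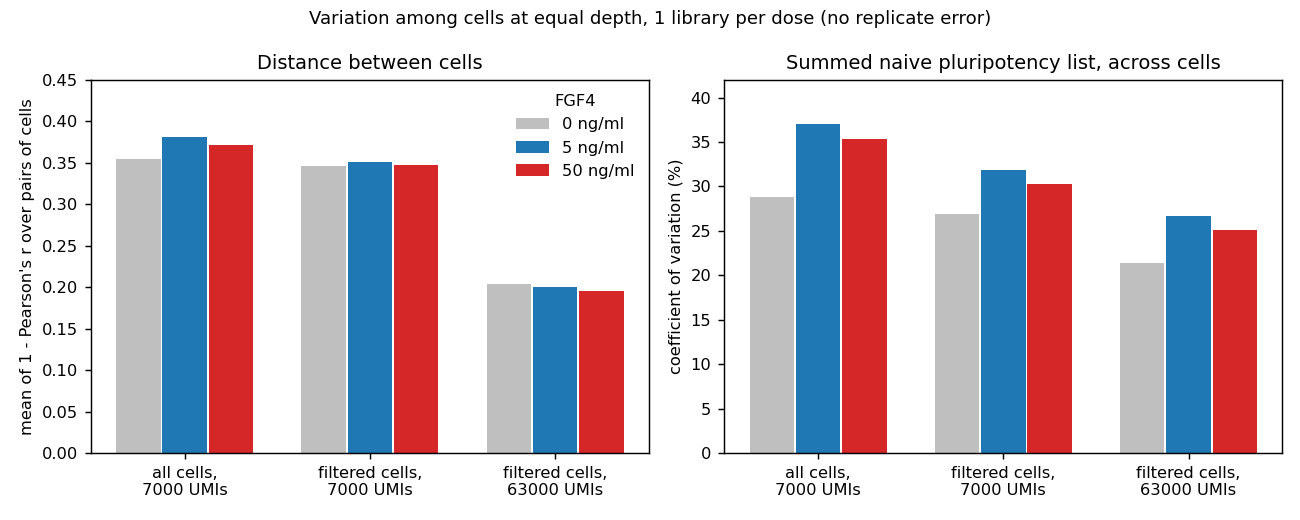
Mean distance between cells (1 minus Pearson correlation) and coefficient of variation of the summed naive list (%) at 0, 5 and 50 ng/ml FGF4, as bars, for all cells, filtered cells and filtered cells thinned to 63000 UMIs. The distance was 0.354, 0.381 and 0.372 over all cells but 0.204, 0.201 and 0.196 in the last setting. The coefficient of variation of the naive list was greater with FGF4 in all 3 settings, where its mean level was not matched between doses.

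Clustering within each library gave 5, 6 and 7 groups at resolution 0.5 and 9, 9 and 11 at resolution 1 for 0, 5 and 50 ng/ml. All cells were used, without the cell filter, and groups of shallow, mitochondria-rich cells were among those counted. At resolution 0.5 their median mitochondrial shares were 98.2% at 0, 93.0% and 21.8% at 5, and 93.2% and 22.6% at 50 ng/ml. The libraries also differed in cell number, so no dose order was read from the number of groups. No group had enough raised markers for any of the 8 cell identities tested, naive and formative among them, so all were left unnamed. Their sizes were not compared between libraries.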

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

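The settings with filtered cells thinned to 63000 UMIs and the naive-list variation alternatives were chosen only after the planned results were seen. The other alternatives in this section were fixed before. No paired analysis was possible because each dose was 1 library. Settings that recomputed a main result from the same libraries were read for sign and for a difference of more than 1.5-fold.

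Counts of genes depended on the level and fold limits, because these define what is counted. With a minimum of 5 CPM, 200 genes were higher and 202 lower at 5 ng/ml than without FGF4, 249 higher at 50 ng/ml, and 17 higher and 10 lower between 50 and 5 ng/ml. The number of genes at least 2-fold lower, 50 v 0 ng/ml, was 327 with that minimum. With a minimum of 100 CPM these were 16 and 12, 26 and 20, and 0 and 0. At 1.5-fold they were 211 and 227, 257 and 340, and 10 and 19, and the doses then shared 175 higher and 219 lower genes. At 3-fold they were 30 and 22, then 53 and 32, with 0 lower between 50 and 5 ng/ml. Between 50 and 5 ng/ml the mean share per cell gave 11 higher genes, the cell filter gave 2 and median-of-ratios scaling gave 1 lower gene. The other settings left the counts within 1.5-fold. Of the 33 alternative counts of higher genes 13 moved, and of the 33 of lower genes 13 moved.

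The distance between cells depended on the cells and depth used, and 18 of its 48 alternative values moved and 14 took the opposite sign. Leaving out mitochondria-rich cells and cells of extreme depth gave differences of 0.00506 for 5 minus 0, 0.00209 for 50 minus 0 and -0.00297 for 50 minus 5 ng/ml. The size of this drop showed that those cells made up most of the differences of 0.0267 and 0.0174 over all cells. The cause of the other movements was not tested. Thinning to 3500 UMIs gave 0.0484 for 5 minus 0 and 0.0415 for 50 minus 0. Spearman correlation gave 0.0108 and 0.00189. Leaving out cell-cycle genes gave 0.0118 and 0.00876, and -0.00302 for 50 minus 5. A minimum of 1 UMI per cell gave 0.02705 for 50 minus 0, and equal numbers of cells gave -0.0164 for 50 minus 5.

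Filtered cells thinned to 63000 UMIs gave distance differences of the opposite sign against the library without FGF4. These were -0.00350 for 5 minus 0 and -0.00842 for 50 minus 0, and -0.00492 for 50 minus 5 ng/ml. With equal numbers of cells they were -0.00328, -0.00886 and -0.00558, and without called doublets -0.00378, -0.00855 and -0.00477. Without cell-cycle genes the first 2 were -0.00434 and -0.01235. Without mitochondrial and ribosomal genes they were -0.00564, -0.0117 and -0.00601, with a minimum of 1 UMI per cell -0.001005, -0.00635 and -0.00534, and with Spearman correlation -0.00638, -0.0115 and -0.00507. The cause of the opposite sign was not tested.

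The median log2 ratio of Fano factors moved in 14 and took the opposite sign in 10 of 39 alternative values. The cell filter gave 0.00106 for 5 against 0, 0.00252 for 50 against 0 and, with the opposite sign, 0.00392 for 50 against 5 ng/ml. Thinning to 3500 UMIs gave 0.1195 and 0.1134 against 0 ng/ml. Excess variation in place of the Fano factor gave 0.428, 0.345 and -0.109. For 50 against 5 a second seed gave -0.00773, equal numbers of cells -0.0344 and a minimum of 1 UMI per cell -0.0271. The cause was not tested.

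In filtered cells at 63000 UMIs the median log2 Fano ratios were -0.000954 for 5 against 0, -0.00930 for 50 against 0 and -0.00739 for 50 against 5 ng/ml. Equal numbers of cells gave -0.0108 and -0.01775 against 0 ng/ml, and leaving out doublets gave -0.00321, -0.0104 and -0.00531. Excess variation gave -0.0601, -0.0789 and -0.0251, and no matching of means gave 0.00382 and -0.00707 against 0 ng/ml. These ratios lay close to 0, and the cause was not tested.

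Of 567 alternative list medians, 3 took the opposite sign of a median that lay outside the middle 95% of matched random lists. A further 117 moved, mostly for lists near 0, and these include the opposite signs of lists inside that range, such as the Wnt and germline lists. The median log2 ratio of the immediate early and dissociation response list, 50 v 5 ng/ml, was 0.003436 with the mean share per cell. The trophectoderm list, read over members with at least 20 CPM, was -0.5625 at 5 and -0.8226 at 50 ng/ml, since Cdx2 and Eomes did not reach that level. FGF and ERK medians at 50 ng/ml ran from 1.42 to 1.63 over the alternatives, formative medians from 0.905 to 1.01, general pluripotency medians from 0.685 to 0.844. The median log2 ratio of the naive pluripotency list, 50 v 0 ng/ml, ran from -0.887 to -0.382.

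Fano factors of lists moved in 256 of 696 alternative values and shares of cells in 185 of 207. This was mainly at full depth or 63000 UMIs, where most cells have more UMIs to show. With each naive member left out in turn at 3 doses, the coefficient of variation of the list stayed within 1.5-fold in 63 of 63 values. The order of the doses was less stable, as without Dppa5a it was 33.8% at 5 and 35.3% at 50 ng/ml, instead of 26.6% and 25.1%. Cluster numbers moved in 2 of 3 libraries at resolution 1.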

Other observations

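Genes outside the named rule and the text above are described first here and were picked after the values were seen, as were the tests on mitochondria-rich barcodes, on a wider spread among intact cells, on the share of 2-cell-like UMIs in few cells, on scaling of imprinted genes and on Egr1. At 50 ng/ml relative to no FGF4, the creatine kinase Ckb was 221 CPM against 789 CPM, or 3.57-fold lower (3.50 to 3.63). The lactate dehydrogenase Ldhb was 2.97-fold lower (2.91 to 3.03), the carnitine palmitoyltransferase Cpt1a 3.55-fold lower (3.27 to 3.85) and the hexokinase Hk1 3.06-fold lower (2.79 to 3.35). Ldha was higher, so the Ldha and Ldhb forms stood on opposite sides. Also lower were the surface-protein gene Cd9, 2.17-fold lower (2.11 to 2.24) at 97.7 CPM against 212 CPM, and Cd24a, 2.29-fold lower (2.16 to 2.43). Ifitm1 was 2.76-fold lower (2.70 to 2.82) and the neural adhesion gene Ncam1 4.03-fold lower (3.66 to 4.45).

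On the higher side at 50 ng/ml was the growth-factor gene Bmp4, at 26.7 CPM against 4.45 CPM or 6.01-fold higher (5.18 to 7.01). The BMP targets lay on both sides, with 3 of 5 higher, Id1 and Id3 among them, and 2 lower, Id4 among them. Fgfbp1, which encodes an FGF-binding protein, was 5.49-fold higher (4.74 to 6.39) and Cntfr, a receptor subunit related to the LIF pathway, 6.54-fold higher (5.57 to 7.71). The X-linked homeobox gene Rhox5 was 3.02-fold higher (2.87 to 3.19), and the cyclin Ccnd1, by contrast with Ccnd2, was 1.27-fold higher (1.23 to 1.31). The primitive-endoderm regulator Gata6 had 15, 5 and 178 UMIs at 0, 5 and 50 ng/ml, too few in CPM terms to be read as an order. A Gata6 UMI was present in 3.49%, 0.572% and 2.56% of cells without thinning, so the 178 UMIs lay in few cells. Gata4 had 14, 24 and 20 UMIs and Sox17 had 11, 4 and 23.

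The greater distance between cells with FGF4 was weighed against cell quality. Cells with more than 50% mitochondrial UMIs made up 2.14% (0.930 to 4.18), 8.58% (6.81 to 10.6) and 9.03% (7.30 to 11) of the libraries at 0, 5 and 50 ng/ml. Without mitochondria-rich and shallow barcodes the difference for 5 minus 0 ng/ml was 0.00506, in line with those barcodes as the main source of the distance over all cells. Whether intact cells had a wider spread over all genes with FGF4 could not be decided. With the cell filter alone, the difference for 50 minus 0 ng/ml was 0.00209, a slightly wider spread. In filtered cells thinned to 63000 UMIs, a depth chosen after the results were seen, it was -0.00842. That depth left out a further 17 of 359, 47 of 706 and 79 of 798 filtered cells at 0, 5 and 50 ng/ml. The settings thus differed in both cells and depth and gave opposite signs.

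Transcripts of the 2-cell-like programme were lower at 5 than at 0 or 50 ng/ml, with Zscan4c at 11.8, 3.15 and 18.7 CPM, and the list median log2 ratios were -1.72 at 5 and 1.06 at 50 ng/ml relative to 0. The 1% of cells with most of these UMIs held at least 95.4% of them in every library. Cells with at least 3 of the genes were 1.39% (0.454 to 3.22), 0.708% (0.230 to 1.64) and 0.877% (0.353 to 1.80) of filtered cells, and these intervals overlapped. These values are consistent with a handful of cells setting the level in each library, so no dose order was read. The same few cells also set the variation of some other genes, a test written before its result. When they were left out, 7 of the 10 genes with the largest drop of Fano factor came within 2-fold, and Nelfa at 0 ng/ml went from 51.4 to 1.31, whereas Snhg1, Zfas1 and Terf2ip did not. Single cells carried those too, since without the richest cell of each library, a setting added after the result, the ratios were 1.09 for Snhg1, 1.31 for Zfas1 and 2.17 for Terf2ip, down from 8.37. Of the 10 genes with the largest gain of Fano factor, leaving out the 2-cell-like cells brought 0 within 2-fold at 5 ng/ml. At 50 ng/ml it brought 4, of which 2 already were, and the others were Zscan4-ps2 and Slc7a14. Those cells held 94.6% of the Zscan4-ps2 UMIs at 50 ng/ml, so its outcome was all but fixed. Without the richest cell of each library 7 of 10 came within 2-fold at 5 ng/ml. At 50 ng/ml 6 of 10 were within 2-fold, of which 2 already were. Single cells thus carried most of these gains at 5 ng/ml and some at 50 ng/ml.

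Higher Meg3 and Rian with FGF4 could come from a mix of cells with and without these transcripts at 0 ng/ml, or from a lower level in every cell. Of 342 filtered cells at 0 ng/ml thinned to 63000 UMIs, 36.8% (31.7 to 42.2) had no Meg3 UMI. A common level with counting noise alone would give 4.74%, and a full mix 78.7%. The first value leaves out all other variation among cells. At 50 ng/ml 5.84% of cells had no Meg3 UMI, where counting noise alone would give 0.000136%. An excess over counting noise is therefore no sign of a mix. A mix and a lower level in every cell cannot be told apart. The interval spans the bound of 40% fixed beforehand, and a partial mix lies between the 2 readings. Rian stood at 54.1%, where a common level with counting noise alone would give 37.9% and a full mix 80.1%. Scaling or mitochondria-rich barcodes did not account for the higher imprinted genes, as the lowest median log2 ratio over the alternatives was 1.11 at 50 ng/ml. Snrpn, with 0.877% of cells lacking a UMI at 0 ng/ml against 62.5% in a full mix, did not have this pattern.

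The greater relative variation of naive genes with FGF4 may arise from cells placed along an axis from naive to formative expression, which is a hypothesis only. The correlation across cells between the summed naive and formative lists was -0.110, -0.276 and -0.394 at 0, 5 and 50 ng/ml, a difference of -0.284 between 50 and 0 ng/ml. With counting noise allowed for, on sums without logs, it was -0.161, -0.376 and -0.488. Most formative members did not vary more, as 2 of 7 had a greater excess variation at 50 ng/ml than without ligand, though levels were not matched. The pattern did not come from Dppa5a alone, because without it the coefficient of variation was 24.3%, 33.8% and 35.3%. Among single naive genes, Jam2 had a squared coefficient of variation beyond counting noise of 0.199, 0.527 and 1.09, and Esrrb of 0.0697, 0.172 and 0.273.

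Lower Egr1 with FGF4 ran against its place as an ERK target and might reflect a weaker detachment response, since dissociation can induce immediate early genes. Only 5 of the 12 genes of the immediate early and dissociation list were measured, Egr1 among them. Fos, Jun, Junb and Atf3 were among those that did not reach 5 CPM in any library, so the list covers little of that response. Of the other 4 measured genes, 2 (Klf6 and Btg2) were at least 1.5-fold lower at 50 ng/ml, a number between the bounds set. A weaker detachment response and an effect of FGF4 thus cannot be told apart. The detachment enzyme of each library was not given in the sources used here, which keeps this open.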
